A study of Homo sapiens with 39 samples.

How the data were processed

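Skin biopsies of 6 patients with atopic dermatitis from a Phase 2a trial of a topical gel were profiled by RNA sequencing. Per the labels' protocols, total RNA was extracted with a kit for fibrous tissue, and libraries were made by tagmentation and enriched with an exome capture panel, so the table holds almost only protein-coding genes (19685 of 20267 in GENCODE 29; 4 had no match). Per the submitters' processing notes the genome build was hg38. The aligner, the counter and the scaling method were not given in the sources used here. Sequence reads were not analysed here.

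The table holds 39 columns, 1 per library, and no column was without a sample. Its values are treated as a signal, deposited after division of estimated reads by 1 factor per library. The file is named as raw counts, but the deposited values are not whole. In each library 89.7% to 92.4% of the low values (up to 20 steps) were whole multiples of 1 step within a tolerance of 0.02, and the step ran from 0.553 to 1.739 between libraries. The deposited totals ran from 8902550 to 12576335 (median 10491096). Dividing by the step gave an estimated 7.14 to 18.25 M reads per library (median 9.83). The median ratio of each library to the geometric mean of all libraries was 0.991 to 1.01, so the values entered the tests with the deposited scaling. FLG alone took 0.4% to 8.48% of the total of a library, and its 10 largest genes together 8.9% to 22.3%.

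Replicate numbers are the patient numbers of the titles. Groups were non-lesional skin of day 1 and the lesion assigned to atuzabrutinib or to placebo on days 1, 15 and 29. The labels do not state whether the biopsies of day 1 were taken before the first dose or which visits fall in the blinded and which in the open-label period, and no non-lesional library of days 15 and 29 was analysed here. Pairing was checked on deviations from the group means. Their mean correlation was 0.45 within a patient and −0.11 between patients, the lowest mean within a patient was 0.31, and 38 of 39 libraries matched their own patient best. The patient is therefore a block in the model, as the intra-patient design of the labels implies. The highest correlation of log2 values between 2 libraries was 0.985, and 0 libraries failed to match their patient on sex-linked genes.

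The design fixed beforehand named a quasi-likelihood test for whole reads, with trimmed-mean scaling and a filter by group. Because the values were not whole, the test was limma with a trend instead (limma 3.58.1, R 4.3.3). It was fitted to log2 of the value plus 1 for 15311 genes with a value of at least 10 in at least 5 libraries, with group and patient as terms, all 39 libraries, robust variance moderation, 27 residual and a median of 4 prior degrees of freedom. Benjamini-Hochberg adjustment was made within each comparison, and a gene was called at an adjusted p below 0.05. There were 10 comparisons: lesional (mean of both lesions) against non-lesional skin on day 1, each lesion at days 15 and 29 against day 1, the difference between the lesions of these changes at each day, and the atuzabrutinib against the placebo lesion on each day. Patients lacking a biopsy stayed in the model, and per-patient counts use those with every biopsy of a comparison. Chance alone gives 766 of 15311 genes an unadjusted p below 0.05.

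Genes were named by a rule fixed beforehand. It took up to 10 called genes per direction with the largest change, with a log2 of the mean CPM (values scaled to the library total) of at least 1 and the same sign in every patient. Where fewer than 5 were called it took the 5 smallest p values per direction. Up to 3 called members of each list were added, or the 2 with the smallest p, and BTK, IL13, CCL17, CCL18, CCL26, MMP12, S100A8, KRT16, FLG, LOR and MKI67 always. Genes that can identify a person by sex, HLA type or receptor rearrangement were never named. Some genes picked by the rule are not reported here.

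The 25 gene lists were also fixed beforehand: type 2 cytokines, chemokines and receptors; the IL-17, IL-22 and IL-36 axis with antimicrobial genes; interferon and type 1 response; barrier and terminal differentiation; epidermal hyperplasia; epidermal lipid synthesis; BTK and B cell or Fc receptor signalling; proliferation; itch; stress of dissociation, ischaemia and RNA handling; and markers of T cells, B and plasma cells, mast cells and basophils, dendritic and Langerhans cells, monocytes and macrophages, neutrophils and eosinophils, melanocytes, endothelium, fibroblasts and dermal matrix, sebaceous gland, sweat glands, hair follicle, adipocytes, muscle and erythrocytes. For 3 symbols the table's older name was used. Lists were tested on the log2 values, in place of the voom values named beforehand, with camera (preset correlation 0.01, or estimated), which compares a list with all other genes, and with fry. The adjusted p of fry tests whether the genes of a list move one way on balance, its mixed p whether they change in either direction, and neither compares the list with other genes. Adjusted p values of lists are over the 25 lists of a comparison, and the mean of a list per patient was tested with an exact two-sided sign-flip test.

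The lesional score of a biopsy is the mean log2 value (plus 2) of up to 100 genes higher in lesional skin minus that of up to 100 lower ones, taken by p among called genes of the other lesion. Changes of the score were tested with exact two-sided sign-flip tests, which cannot go below 0.0312 with 6 patients or 0.0625 with 5. The gene tests were tested on simulated data with the real patients, depths and spreads and known 2-fold and 4-fold differences in 200 genes each. At 2-fold they recovered 69% of lesional differences and 62.3% to 70% of changes over time, and 4% to 6.1% of calls were false. These shares are for independent simulated genes and need not hold in the real data. There, labels exchanged within patients gave up to 1714 calls. For lists only a 2-fold rise of the T cell list was simulated, which camera with the preset correlation called (adjusted p = 2.9e-06) with 0 other lists. The simulated genes were independent, so this does not test the preset correlation. Alternatives fixed beforehand were no filter, a stricter filter, size factors from median ratios, voom on the estimated reads, scaled to the library total, with the patient as a random effect, no patient block, the lesion as block, only the compared groups, averaged lesions of a patient, each patient left out, and other settings of the lists and the score. Alternatives chosen after seeing the data were 2 other pseudocounts, quantile normalization, scaling to the library total, a filter at a value of 50, and covariates for estimated reads, the total of 401 olfactory receptor genes (a sign of background capture), the stress list and the fibroblast list.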

Results

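Gene expression was measured in skin biopsies from 6 patients with atopic dermatitis, an inflammatory skin disease driven largely by type 2 cytokines. Each patient had 2 lesions, of which 1 was assigned to a gel with atuzabrutinib, a reversible covalent inhibitor of Bruton's tyrosine kinase (BTK), and the other to placebo gel. The 39 libraries fell into 7 groups. Non-lesional skin of day 1, the atuzabrutinib lesion of days 1 and 15 and the placebo lesion of day 1 had 6 libraries each, and the placebo lesion of day 15 and both lesions of day 29 had 5 each. Libraries held an estimated 7.14 to 18.25 M reads (median 9.83), and 15311 of 20267 genes were tested. The day 1 libraries were the most uneven in depth, with 13.25 ± 4.14 M reads in non-lesional skin, 11.56 ± 4.37 in the placebo lesion and 8.84 ± 0.83 in the atuzabrutinib lesion (mean ± SD, n = 6 each). The labels name a blinded and an open-label period but do not state which visits fall in each, so a lesion is called by its assignment and not by the gel it received at a visit. Changes are log2 values of the model ± SE.

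BTK, the target of the drug (ENSG00000010671, chromosome X 101349447 to 101390796 in hg38), had a mean scaled value of 92.3 ± 26.2 in non-lesional skin, 99.4 ± 53.1 in the atuzabrutinib lesion and 158 ± 159 in the placebo lesion on day 1 (SD, n = 6 each). The last mean rested on 1 library at 463, and the medians were 86.4, 92.8 and 88.6. It passed the test in none of the 10 comparisons, and its largest change within a lesion was 0.65 ± 0.27 in the atuzabrutinib lesion at day 15 (adjusted p = 0.17, higher in 5 of 6 patients). IL13, which encodes a central type 2 cytokine, had group means of 0.49 to 1.25 and stayed below the filter. CCL26, which encodes an eosinophil-attracting chemokine, had group means of 1.17 to 3.38 and stayed below it as well, so neither was tested.

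The comparison of lesional with non-lesional skin on day 1 asked how diseased skin differed within the same patients. The collagenase gene MMP1 rose by 4.16 ± 0.90 (17.9-fold, adjusted p = 0.012) and the stromelysin gene MMP3 by 4.10 ± 1.08 (0.027). FOSL1, a subunit of the AP-1 transcription factor, rose by 3.80 ± 0.78 (0.01), and SOCS3, a feedback inhibitor of cytokine receptors, by 3.15 ± 0.50 (0.0035). Higher transcripts also came from the aggrecan-degrading protease gene ADAMTS4 (3.55 ± 0.57, 0.0035), the cytokine gene IL6 (2.89 ± 0.69, 0.018) and the cytidine deaminase gene APOBEC3A (3.26 ± 0.83, 0.024). Among lower genes taken by the naming rule, the largest drop was in WIF1, a secreted Wnt inhibitor (−2.23 ± 0.46, 0.01). Other lower genes included ZBTB16, a transcription factor (−1.41 ± 0.30, 0.012), MYOM2, a sarcomere protein (−1.40 ± 0.30, 0.012), and CDNF, a neurotrophic factor (−1.35 ± 0.24, 0.0052). All of these genes moved the same way in 6 of 6 patients, as the naming rule required.

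In the list of type 2 cytokines, chemokines and receptors, 3 of 17 tested members rose and none fell (4 higher adjusted over the list alone). They were IL4R, the shared receptor chain of IL-4 and IL-13 (1.0 ± 0.21, adjusted p = 0.011, 6 of 6 patients), CRLF2, the receptor of TSLP (1.09 ± 0.33, 0.039, 6 of 6), and the chemokine gene CCL18 (2.59 ± 0.79, 0.043, 5 of 6). CCL17, a ligand of the T cell receptor CCR4, was at 0.15 ± 0.84 (0.93). Of the 20 tested genes of the IL-17, IL-22 and IL-36 axis and of epidermal antimicrobial defence, 3 rose (12 adjusted over the list alone). These were the neutrophil chemokine gene CXCL8 (2.91 ± 0.80, 0.031), S100A7A (3.35 ± 0.93, 0.032) and IL20 (2.09 ± 0.61, 0.037, 4 of 6 patients). The mean log2 values of CXCL8 (1.79) and IL20 (1.56) over all libraries were low. S100A8, a subunit of calprotectin, was at 2.16 ± 0.89 and did not pass (0.11, 6 of 6). In the interferon and type 1 list 4 of 25 rose (9 over the list alone), among them OASL, an interferon-induced antiviral gene (2.39 ± 0.46, 0.0074), the IL-12 receptor gene IL12RB2 (0.96 ± 0.23, 0.019) and the cytotoxic granule gene GZMB (1.79 ± 0.54, 0.04). The itch list had 3 of 14 higher, among them OSMR, the receptor chain for oncostatin M and IL-31 (0.83 ± 0.17, 0.0083), and the histamine receptor gene HRH1 (1.53 ± 0.36, 0.017).

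Among genes of epidermal hyperplasia and the stressed cornified envelope, 9 of 24 rose and none fell (13 adjusted over the list alone). KRT16, a keratin of activated epidermis, rose by 2.79 ± 0.70 (6.91-fold, adjusted p = 0.024, 6 of 6 patients), and LCE3E, a cornified envelope gene, by 2.02 ± 0.56 (0.032). The list of barrier and terminal differentiation genes had only IVL (involucrin) higher among 38 (1.12 ± 0.34, 0.042, 5 of 6; none over the list alone). FLG (filaggrin), at −0.30 ± 0.29 (0.52), and LOR (loricrin), at −0.50 ± 0.35 (0.36), did not pass. No gene of the 24 in epidermal lipid synthesis passed, with the ceramidase gene ACER1 at −0.49 ± 0.18 (0.075). None of the 22 proliferation genes passed either, with RRM2 at 1.21 ± 0.51 (0.12) and MKI67 at 0.47 ± 0.37 (0.42). In the list of BTK and of B cell receptor or Fc receptor signalling, 2 of 24 rose, the Src-family kinase gene LYN (0.89 ± 0.25, 0.035) and BCL10, which relays antigen receptor signals to NF-kB (0.59 ± 0.19, 0.049), each in 5 of 6 patients.

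Markers of other cells in the biopsy moved in part. The high-affinity IL-2 receptor gene IL2RA rose among 20 T cell markers (1.93 ± 0.59, adjusted p = 0.043; 4 members over the list alone). CXCR1 and FPR1, receptors on neutrophils, rose among 8 granulocyte markers (2.12 ± 0.53, 0.022, and 2.31 ± 0.65, 0.033), and SELE, the endothelial adhesion molecule E-selectin, among 12 endothelial markers (2.59 ± 0.51, 0.0083). Of 15 dendritic and Langerhans cell markers, CD207 (−0.89 ± 0.27, 0.04, 5 of 6 patients) and CD1A (−0.64 ± 0.20, 0.047, 4 of 6) fell (2 higher and 2 lower over the list alone). KIT, a receptor of mast cells and melanocytes, fell (−0.49 ± 0.14, 0.037) and was the only call among 15 mast cell and among 10 melanocyte markers. No monocyte or macrophage marker of 15 passed over all genes, but 8 were higher over the list alone. The sweat gland list had KRT77 lower (1 of 12; −0.94 ± 0.30, 0.048) and the hair follicle list KRT15 (1 of 14; −0.76 ± 0.23, 0.042). No marker of B and plasma cells (7), fibroblasts (15), sebaceous gland (15), adipocytes (11), muscle (10) or erythrocytes (5) passed.

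The list of dissociation, ischaemia and RNA handling stress moved with these gene groups. It had 6 of 20 members higher (9 over the list alone), with ZFP36, which destabilises cytokine mRNA, at 1.18 ± 0.22 (adjusted p = 0.0074), the AP-1 gene JUNB at 0.99 ± 0.20 (0.0083) and the metallothionein gene MT2A at 1.52 ± 0.32 (0.011). Its mean log2 value was 8.85 ± 0.37 in non-lesional skin and 9.54 ± 0.74 and 9.42 ± 0.54 in the atuzabrutinib and placebo lesions (SD, n = 6 each). By fry, which asks whether the genes of a list move one way on balance, 3 of 25 lists moved up. They were the IL-17, IL-22 and IL-36 list (median 1.41, adjusted p = 0.03), the hyperplasia list (1.49, 0.03) and the stress list (0.61, 0.022). Each was higher in 6 of 6 patients (exact two-sided sign-flip p = 0.0312, the smallest possible). By camera with a preset correlation, which compares a list with all other genes, 13 lists were called (12 without the patient block, where the barrier list dropped out at adjusted p = 0.087). No camera call of any comparison held with an estimated correlation, where the lowest adjusted p here was 0.54. The hair follicle list had a median of 0.11 beside a mean of −0.03 and a downward test (adjusted p = 0.57).

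Across all genes, 635 were higher and 586 lower in lesional skin, 1221 in total, and 753 of them moved the same way in every patient. The placebo lesion alone gave 964 calls against non-lesional skin and the atuzabrutinib lesion alone 12. The share of higher calls was 52%, but 35.8% with voom and 37.3% scaled to the library total. The count was 11 without the patient block. With fewer libraries to estimate the spread, it was 490 with only the 3 groups compared and 0 with both lesions of a patient combined into 1 value. It was 810 without replicate 1, 538 without replicate 5 and 0 without replicate 3 or 6, and 1 with the stress list as a covariate.

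**Figure D1:**
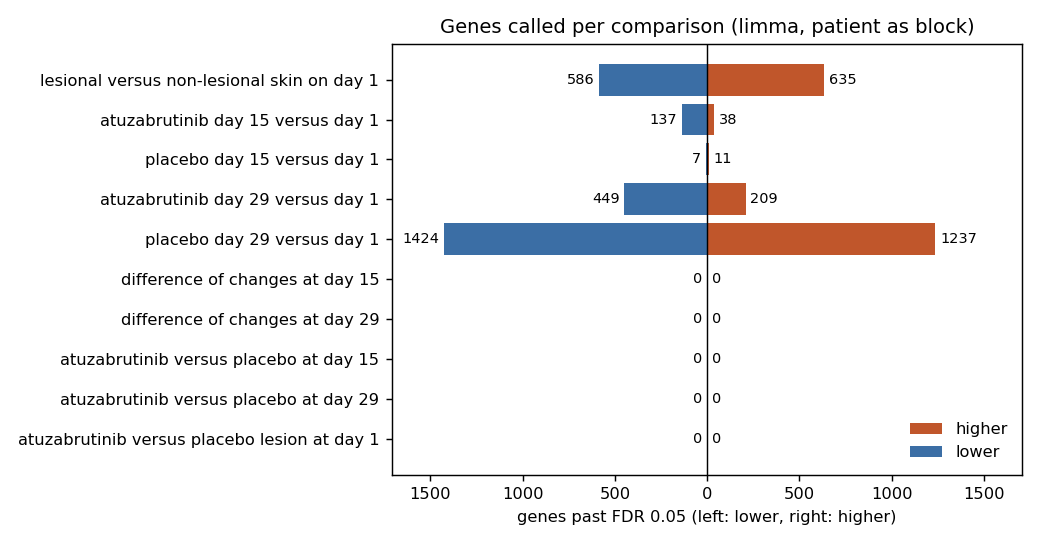
Bars give the number of genes called higher or lower (limma, adjusted p < 0.05, of 15311 tested) in each of the 10 comparisons. The 5 comparisons between the atuzabrutinib and placebo lesions had 0 calls.

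**Figure D2:**
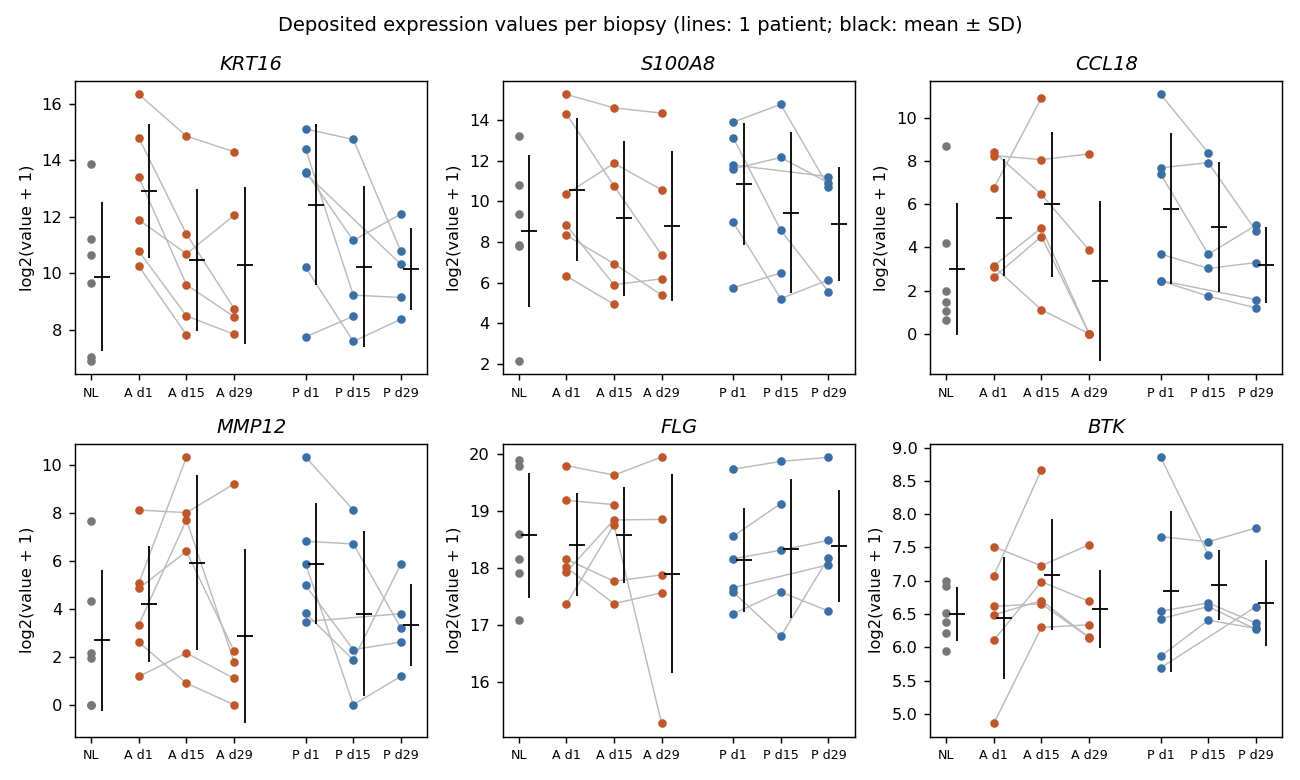
Each point is 1 biopsy and each line joins the biopsies of 1 lesion, with log2 of the deposited value plus 1 on the vertical axis and the 7 groups (NL non-lesional, A atuzabrutinib and P placebo lesion, d day) on the horizontal axis, and black marks for mean ± SD. The mean KRT16 of the lesions was above that of non-lesional skin in 6 of 6 patients on day 1, while BTK passed the test in no comparison.

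The change from day 1 to day 15 in the atuzabrutinib lesion asked which genes differed between these visits. Among genes taken by the naming rule, FOSL1 fell the most (−4.91 ± 0.90, adjusted p = 0.01). It was followed by FGFBP1, which releases fibroblast growth factors from the matrix (−2.76 ± 0.47, 0.0096), the immediate-early nuclear receptor gene NR4A1 (−2.75 ± 0.48, 0.0096) and the EGF receptor ligand gene AREG (−2.62 ± 0.63, 0.041). Lower transcripts also came from CXCR1 (−2.46 ± 0.61, 0.043), HAS3, a hyaluronan synthase (−2.40 ± 0.60, 0.043), SELE (−2.39 ± 0.59, 0.043) and SOCS3 (−2.34 ± 0.58, 0.043). Those that rose included CD1E, a lipid-antigen protein of dendritic cells (1.44 ± 0.36, 0.044), LY75, the endocytic receptor DEC-205 (0.86 ± 0.21, 0.041), SP140, a nuclear body protein of leukocytes (1.34 ± 0.33, 0.041), TRAF1, an adaptor of TNF receptors (0.94 ± 0.23, 0.041), and TXNIP, an inhibitor of thioredoxin (0.87 ± 0.22, 0.043). Each moved the same way in 6 of 6 patients, which the naming rule required.

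By list, 2 of 24 hyperplasia genes fell in this lesion (5 adjusted over the list alone), namely FOSL1 and the Eph receptor gene EPHA2 (−1.16 ± 0.28, adjusted p = 0.041, 5 of 6 patients). The list's median was −1.18 and it was lower in 6 of 6 patients (exact p = 0.0312), but fry did not call it (0.15). KRT16 stood at −2.44 ± 0.81 (0.099, 6 of 6) and IVL at −1.51 ± 0.39 (0.051, 6 of 6). The dendritic and Langerhans cell list moved up by fry (median 0.87, 0.043; 0.53 with an estimated correlation in camera), with CD1E called over all genes, 7 of 15 over the list alone, and 6 of 6 patients higher (exact p = 0.0312). The stress list moved down (median −0.42, fry 0.023; 0.53 with an estimated correlation in camera), with 6 of 20 lower (9 over the list alone), among them JUNB (−1.31 ± 0.23, 0.0096) and ZFP36 (−1.41 ± 0.25, 0.0098), each in 5 of 6 patients. No T cell marker of 20 passed (list median 0.71, fry 0.46), with CD2 at 1.36 ± 0.50 (0.13). No gene passed in the type 2, interferon, IL-17, lipid, proliferation or BTK lists over all genes. The sebaceous list had a median of 2.15 with no call (fry 0.43).

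In total 38 genes were higher and 137 lower, 175 calls, of which 120 had the same direction in every patient, and 8 of 25 lists were called by camera with the preset correlation (7 without the block). The share of higher calls was 21.7%, but 48.4% with voom and 47.4% scaled to the library total. The count was 6 without the patient block, 7 with the lesion within the patient as block, and 0 with only the groups compared or with the stress list as a covariate. It was 588 without replicate 1, 369 without replicate 2, 10 without replicate 6, and 0 without replicate 3, 4 or 5.

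In the placebo lesion, few genes passed over the same interval. ADAMTS4 (−3.37 ± 0.70, adjusted p = 0.043), SOCS3 (−3.07 ± 0.62, 0.043) and BCL3, a nuclear regulator of NF-kB (−1.44 ± 0.29, 0.043), fell. The 7 lower genes also held CEMIP2, a hyaluronan-degrading protein (−1.27 ± 0.22, 0.043), and TLNRD1, RAP2B and LSM10. Higher were CDNF (1.40 ± 0.29, 0.043), the synaptic scaffold gene DLG2 (1.39 ± 0.28, 0.043), CDKN1B, which encodes the cell cycle inhibitor p27 (0.69 ± 0.14, 0.043), and TIFA, an NF-kB adaptor (0.67 ± 0.14, 0.043), among 11. All 18 moved the same way in 5 of 5 patients. No member of any list passed over all genes. Over the list alone, 4 of 24 hyperplasia genes, 8 of 20 stress genes, 2 of 17 type 2 genes, 2 of 20 IL-17, IL-22 and IL-36 genes and 3 of 14 itch genes were lower, while 2 of 38 barrier genes were higher and 1 lower. Values that did not pass included FOSL1 at −3.70 ± 0.95 (0.062), IL4R at −0.91 ± 0.26 (0.074), CRLF2 at −1.42 ± 0.40 (0.072) and KRT16 at −2.15 ± 0.86 (0.17). Camera with the preset correlation called 14 lists (8 without the block), with the smallest p for hyperplasia (median −1.24), stress (−0.34), monocytes and macrophages (−1.16) and sweat glands (1.61), and fry called none (lowest adjusted p = 0.2, stress list). The itch list had a median of 0.03 beside a mean of −0.13 and a downward test. The count was 0 without the patient block, with the lesion as block, with only the groups compared, and with the stress list as a covariate, but 434 with voom. The share of higher calls was 61.1%, but 70.7% with voom and 78.3% scaled to the library total. The count was 187 without replicate 1, 301 without replicate 2, 6 without replicate 5, and 0 without replicate 3, 4 or 6.

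At day 29 more genes were called against day 1 than at day 15, 658 against 175 in the atuzabrutinib lesion and 2661 against 18 in the placebo lesion. The patients differed between these counts, as replicate 1 had no biopsy of day 29 and replicate 5 no placebo biopsy of day 15. Without replicate 1 the atuzabrutinib counts were 893 at day 29 and 588 at day 15, so the counts do not measure growth over time alone. In the atuzabrutinib lesion the largest drops among genes taken by the naming rule included those of FOSL1 (−6.04 ± 0.95, adjusted p = 0.0021), the AP-1 gene FOSB (−4.51 ± 0.80, 0.0042) and MMP1 (−3.85 ± 1.10, 0.045). SOCS3 (−3.54 ± 0.62, 0.0037), IL6 (−3.22 ± 0.85, 0.034) and the epidermal growth factor family gene EPGN (−3.36 ± 0.91, 0.039) fell as well. SELE (−3.31 ± 0.63, 0.0071) and CXCR1 (−3.17 ± 0.64, 0.0099) were lower too. CD207, the Langerhans cell lectin that had been lower in lesional skin, rose by 1.17 ± 0.33 (0.041). TXNIP rose by 1.19 ± 0.23 (0.0071), PIK3IP1, an inhibitor of PI3-kinase, by 1.53 ± 0.42 (0.04), and the developmental transcription factor gene TBX18 by 1.31 ± 0.32 (0.024). These moved the same way in 5 of 5 patients, as the naming rule required.

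Of 24 hyperplasia genes, 6 fell in the atuzabrutinib lesion at day 29 and none rose (15 lower adjusted over the list alone), with HBEGF, an EGF receptor ligand, at −2.17 ± 0.56 (adjusted p = 0.032), EPHA2 at −1.18 ± 0.30 (0.029) and KRT16 at −3.22 ± 0.86 (0.037, 4 of 5 patients). Of the IL-17, IL-22 and IL-36 list 1 of 20 fell, IL36G (−2.40 ± 0.67, 0.042; 8 over the list alone). In the itch list 3 of 14 fell, HRH1 (−1.84 ± 0.44, 0.023), the warmth-sensing channel gene TRPV3 (−1.23 ± 0.33, 0.037) and OSMR (−0.72 ± 0.20, 0.042), each in 4 of 5 patients. In the interferon list OASL fell (−2.19 ± 0.56, 0.03) and IFIT2, another interferon-induced gene, rose (1.16 ± 0.31, 0.036). In the barrier list IVL (−1.79 ± 0.42, 0.02) and the transglutaminase gene TGM1 (−1.02 ± 0.28, 0.04) fell and the tight junction gene CLDN8 rose (1.02 ± 0.26, 0.026). No type 2 gene passed, with IL4R at −0.84 ± 0.26 (0.054), and that list had a median of 0.03 beside a mean of −0.22 and a downward test. KIT rose (0.72 ± 0.18, 0.024) in the mast cell and melanocyte lists. No gene of the T cell, proliferation, lipid or BTK lists passed.

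The stress list moved with these genes, with 8 of 20 lower (10 over the list alone), among them JUNB (−1.45 ± 0.24, adjusted p = 0.0027) and ZFP36 (−1.62 ± 0.27, 0.0027). By fry, 3 lists moved down, the hyperplasia list (median −1.90, adjusted p = 0.018; 0.47 with an estimated correlation in camera), the stress list (−0.53, 0.0039; 0.35) and the itch list (−0.11, 0.045; 0.51). Camera with the preset correlation called 7 lists, and 7 without the block. The lipid list (median −0.11, mean 0.07, test downward) and the hair follicle list (median −0.34, mean −0.16, test upward) had mixed signs and no call. In total 209 genes were higher and 449 lower, 658 calls, and 536 had the same direction in every patient. Scaled to the library total, the fit called 416 higher and 266 lower. The count was 20 without the patient block, 106 with the lesion as block, 294 with the olfactory receptor total as a covariate, and 0 with only the groups compared or with the stress list as a covariate. It was 20 without replicate 3, 165 without replicate 4, 185 without replicate 6 and 1 without replicate 5.

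In the placebo lesion at day 29, the largest drops among genes taken by the naming rule included MMP1 (−6.19 ± 1.10, adjusted p = 0.0019), MMP3 (−5.90 ± 1.32, 0.005), APOBEC3A (−5.86 ± 1.02, 0.0019), FOSL1 (−5.71 ± 0.95, 0.0013), ADAMTS4 (−4.09 ± 0.70, 0.0016), IL6 (−4.06 ± 0.85, 0.0035) and SOCS3 (−3.96 ± 0.62, 0.001). The largest rise among genes taken by that rule was in LCE5A, a late cornified envelope gene (2.38 ± 0.65, 0.014). CYP3A4, a drug- and steroid-oxidising enzyme (2.29 ± 0.49, 0.0037), BTC, an EGF receptor ligand (2.08 ± 0.63, 0.024), and the anti-inflammatory IL-1 family cytokine IL37 (2.04 ± 0.59, 0.019) rose as well. These moved the same way in 5 of 5 patients, as the naming rule required.

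Of the type 2 list 3 of 17 fell in the placebo lesion at day 29 (3 adjusted over the list alone), IL4R (−1.33 ± 0.26, adjusted p = 0.0022), CRLF2 (−1.50 ± 0.40, 0.012) and the IL-33 receptor gene IL1RL1 (−1.49 ± 0.46, 0.026, 4 of 5 patients). Of the IL-17, IL-22 and IL-36 list 4 of 20 fell (7 over the list alone), including IL20 (−3.13 ± 0.75, 0.0068) and the neutrophil chemokine genes CXCL1 (−2.98 ± 0.73, 0.0075) and CXCL8 (−3.45 ± 0.98, 0.016, 4 of 5). Their mean log2 values over all libraries were low, at 1.56 for IL20, 1.82 for CXCL1 and 1.79 for CXCL8. The interferon list had 4 of 25 lower, with OASL at −2.99 ± 0.56 (0.0021) and ISG15 at −1.55 ± 0.42 (0.013, 4 of 5). The hyperplasia list had 9 of 24 lower (14 over the list alone), with ODC1, the first enzyme of polyamine synthesis, at −2.29 ± 0.53 (0.0057), EPHA2 at −1.25 ± 0.30 (0.0069) and KRT16 at −2.88 ± 0.86 (0.022). The barrier list had 6 of 38 higher and 2 lower (7 and 2 over the list alone), with LCE5A and the serpin gene SERPINB12 (0.84 ± 0.24, 0.016) among the first and IVL (−1.98 ± 0.42, 0.0036) among the second. The itch list had 3 of 14 lower, among them OSMR (−1.10 ± 0.20, 0.0019) and HRH1 (−1.93 ± 0.44, 0.0053), and a median of 0.07 beside a mean of −0.13. LYN fell in the BTK list (1 of 24; −1.03 ± 0.31, 0.023; none over the list alone), MCM4, a replication helicase gene, among 22 proliferation genes (−0.50 ± 0.18, 0.047), and the epidermal lipase gene LIPK rose among 24 lipid genes (0.90 ± 0.26, 0.016).

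Cell markers moved in part in this lesion. CD1A (0.85 ± 0.24, adjusted p = 0.018) and CD1E (1.11 ± 0.39, 0.044) rose among the dendritic and Langerhans cell markers, whose list had a median of −0.02, a mean of −0.03 and an upward test (fry 0.76). FCGR1A, a macrophage Fc receptor (−2.63 ± 0.93, 0.047), CXCR1 (−2.99 ± 0.64, 0.0038) and FPR1 (−2.85 ± 0.79, 0.015) fell, as did the fibroblast markers COL6A3 (−1.28 ± 0.41, 0.033) and THY1 (−1.41 ± 0.50, 0.048). KRT15, a keratin of basal and follicular stem cells (1.33 ± 0.28, 0.0036), and the muscle gene CKM (1.73 ± 0.55, 0.03) rose. No marker of 20 for T cells passed. The stress list again moved with the other genes, with 8 of 20 lower (9 over the list alone), among them MT2A (−2.12 ± 0.39, 0.0019) and the heat-shock gene HSPH1 (−1.46 ± 0.30, 0.0033).

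By fry, 2 lists moved down in the placebo lesion at day 29, hyperplasia (median −1.91, adjusted p = 0.028; 0.81 with an estimated correlation in camera) and stress (−0.40, 0.028; 0.81). Camera with the preset correlation called 11 lists (13 without the block, where the barrier list was lost at 0.095). In total 1237 genes were higher and 1424 lower, 2661 calls, and 2042 of them had the same direction in every patient. The count was 234 without the patient block, 678 with only the groups compared and 25 with the stress list as a covariate. It was 744 without replicate 2, 1180 without replicate 5 and 1470 without replicate 6. Scaled to the library total, 1704 were higher and 1037 lower.

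**Figure D3:**
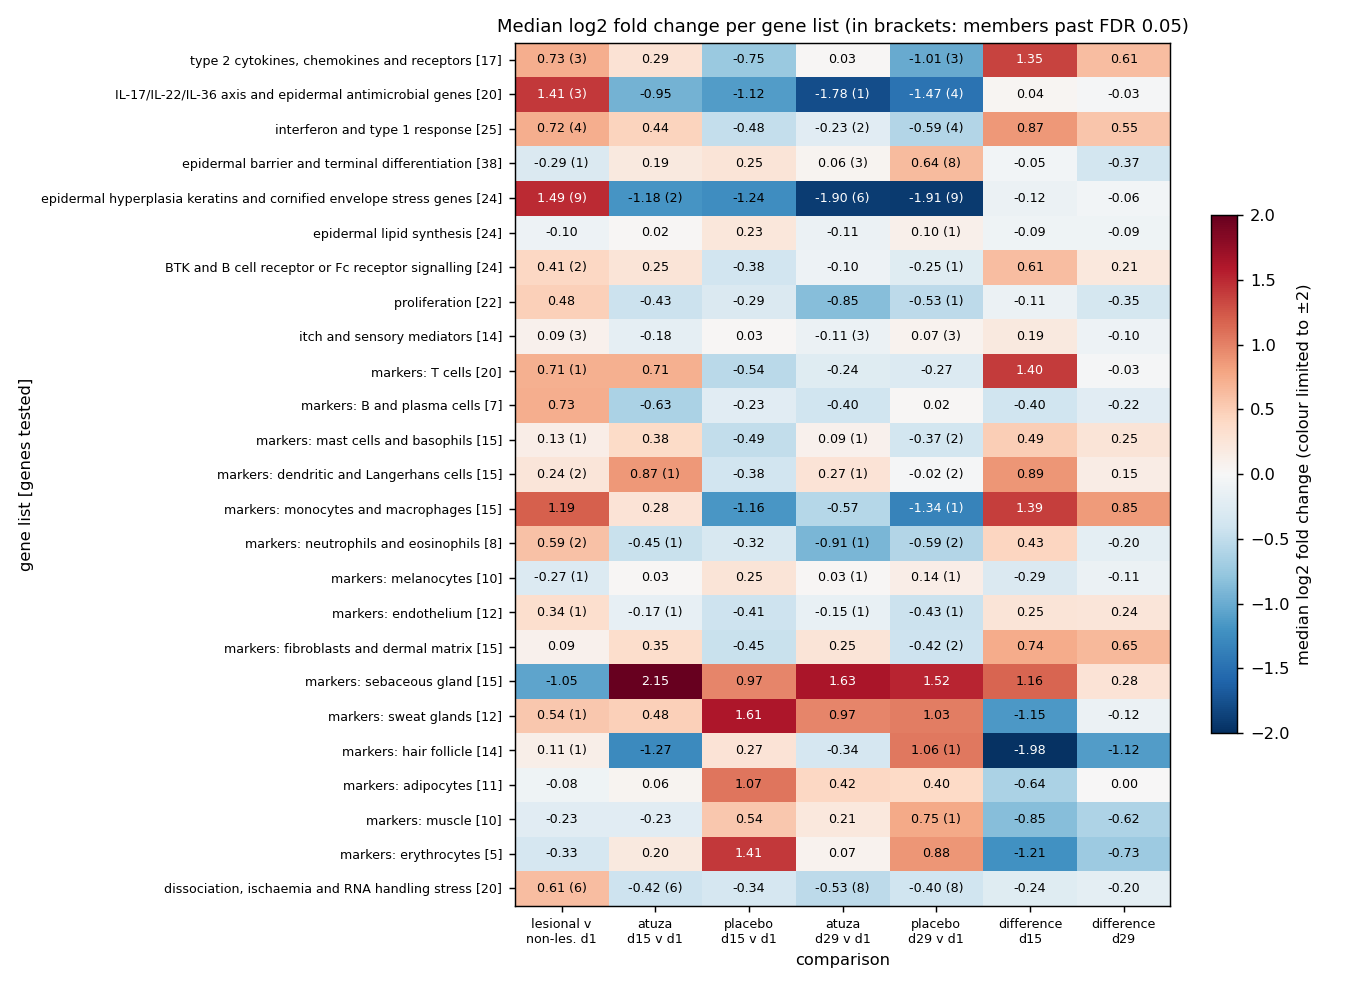
Colour gives the median log2 difference of each fixed gene list (vertical axis) in each comparison shown (horizontal axis), and brackets give the number of members called. The direct comparisons of the lesions on the same day are not shown. The median of the hyperplasia list was 1.49 in lesional against non-lesional skin on day 1, and at day 29 against day 1 of the same lesion it was −1.90 for atuzabrutinib and −1.91 for placebo.

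The genes that fell or rose by day 29 overlapped between the lesions, which shared patients and visits but no library. Of the 449 lower genes of the atuzabrutinib lesion, 372 were also lower in the placebo lesion (41.8 expected if independent), and of its 209 higher genes 151 were also higher (16.9 expected). No gene went in opposite directions. Of the 499 genes higher in the placebo lesion than in non-lesional skin on day 1, 128 were among the 449 that fell in the atuzabrutinib lesion by day 29 (14.6 expected), and 97% of the 499 had a value below 0 there, against 48.3% of all genes. Their median was −0.50, and that of the 465 lower genes 0.40 (96.3% above 0). The expected counts treat genes as independent and the lesions as unrelated, so they are no test of chance.

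The test of the drug against placebo compared the change in the atuzabrutinib lesion with the change in the placebo lesion. No gene passed at day 15 or at day 29, in any setting or without any patient. By limma, 533 genes had an unadjusted p < 0.05 at day 15 and 243 at day 29, where chance alone gives 766, and by voom 406 and 250 with 0 calls. Leaving out the patient block gave 51 and 45. At day 15 the genes with the smallest p values included on the higher side TLDC2 (2.66 ± 0.65, adjusted p = 1, 5 of 5 patients) and TRAF1 (1.38 ± 0.34, 1, 5 of 5), and on the lower side the ribosomal protein gene RPS6 (−0.41 ± 0.13, 1). At day 29 they included the stromelysin gene MMP10 (3.32 ± 1.07, 1, 5 of 5) and C1QTNF9B (−1.35 ± 0.34, 1, 5 of 5). BTK stood at 0.71 ± 0.39 and 0.31 ± 0.40, KRT16 at −0.29 ± 1.18 and −0.33 ± 1.20, and MMP12, a macrophage elastase gene, at 4.13 ± 1.82 and 1.22 ± 1.86 at days 15 and 29 (adjusted p = 1). The BTK values use the placebo lesion of day 1, where 1 library was at 463 beside a median of 88.6. In simulated data of the same design, 40.2% of 2-fold and 78% of 4-fold differences were recovered at day 15, and 43.5% and 76.5% at day 29. That simulation held independent genes with 200 changed at each fold. The real differences had fewer unadjusted p values below 0.05 than chance gives, so their spread need not be that of the simulated data. The cause of this shortfall was not tested. Fewer changed genes make the adjusted threshold stricter, so these shares do not give the recovery of an effect on few genes.

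In the difference of changes at day 15, list medians had both signs and no list member was called. The T cell list had a median of 1.40 (camera adjusted p = 3.3e-13 with the preset correlation, 0.26 with an estimated correlation, fry 0.36), with CD3E at 1.79 ± 0.67 (adjusted p = 1), and it was higher in 4 of 5 patients (exact p = 0.125). Its mean per patient was 1.48, and 0.79 without replicate 1. The monocyte and macrophage list had 1.39 (0.28 with an estimated correlation), the type 2 list 1.35 (0.2), the dendritic cell list 0.89 (0.2), the interferon list 0.87 (0.29), the fibroblast list 0.74 (0.51) and the BTK list 0.61 (0.28). On the negative side were the hair follicle list at −1.98 (0.56), the sweat gland list at −1.15 (0.56) and the B and plasma cell list at −0.40 (0.87). Fry called none of the 25 lists in either difference, camera with the preset correlation called 14 at day 15 (13 without the block) and 8 at day 29 (9), and all 14 and 8 were lost with an estimated correlation. On day 1, 15 lists were called by camera with the preset correlation between the lesions (16 without the block, none by fry), among them the T cell list in the opposite direction (median −0.45, adjusted p = 0.61 with an estimated correlation). The monocyte and macrophage (−0.79), fibroblast (−0.38), mast cell (−0.29) and sebaceous gland lists (−1.31) were lower in the atuzabrutinib lesion in 6 of 6 patients on day 1 (exact p = 0.0312 each, the smallest possible; 0.6 with an estimated correlation).

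Direct comparison of the lesions on the same day gave no call on day 1, 15 or 29. By limma 557, 174 and 123 genes had an unadjusted p < 0.05, and by voom 503, 152 and 117, again with 0 calls. Leaving out the patient block gave 77, 31 and 35. At day 15 the T cell list was higher in the atuzabrutinib lesion in 5 of 5 patients (median 0.84; exact p = 0.0625, the smallest possible; adjusted p = 0.16 with an estimated correlation), with CD3E at 1.20 ± 0.49 (adjusted p = 1). The type 2 (0.70), dendritic cell (0.56) and interferon lists (0.33) were also higher in 5 of 5 patients (exact p = 0.0625 each; 0.32, 0.16 and 0.5 with an estimated correlation). The monocyte and macrophage list stood at 0.63, higher in 3 of 5, and the adipocyte list at −1.12. Camera with the preset correlation called 13 lists (11 without the block). At day 29 the T cell list stood at −0.45 (0.84 with an estimated correlation), and 7 lists were called by camera (3 without the block). On day 1 the gene with the smallest p was C10orf71 (−1.59 ± 0.36, adjusted p = 1, 6 of 6 patients), and BTK stood at −0.40 ± 0.27 (adjusted p = 1). That BTK value includes the placebo library at 463, beside a median of 88.6 in its group.

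A lesional score, the mean log2 value of genes higher in lesional skin minus that of genes lower in it, summarised each biopsy. The genes for a lesion were picked in the other lesion on day 1, so the atuzabrutinib lesion was scored with 100 higher and 100 lower genes and the placebo lesion with only 7 and 5. From day 1 to day 29 the mean change of the score was −1.51 in the atuzabrutinib lesion (SD 0.61, n = 5) and −2.54 in the placebo lesion (SD 0.50, n = 5), below 0 in 5 of 5 patients each (exact two-sided sign-flip p = 0.0625, the smallest possible). At day 15 it was −0.96 (SD 1.06, lower in 5 of 6 patients, exact p = 0.0938) and −1.82 (SD 0.91, lower in 5 of 5, exact p = 0.0625). Where enough genes passed without a patient, the change at day 29 ran from −1.78 to −1.25 for atuzabrutinib and from −2.71 to −1.44 for placebo, and at day 15 from −1.61 to −0.67 and from −2.05 to −1.2. The difference of changes was 1.16 at day 15 (SD 0.76, above 0 in 5 of 5, exact p = 0.0625) and 1.02 at day 29 (SD 0.94, 4 of 5, exact p = 0.125). It mixes the 2 gene sets and depends on which genes are picked. Without the libraries of replicate 1, when 3 genes were left to score the placebo lesion, it was −0.09 and −0.34, and without those of replicates 3, 4, 5 or 6 too few genes passed for a value. With the same genes for both lesions, picked from both, it was 0.53 (exact p = 0.188) and 0.51 (exact p = 0.375), and the lesions differed by −0.31 on day 1 (SD 0.62, n = 6, exact p = 0.312), 0.17 on day 15 (exact p = 0.188) and 0.23 on day 29 (exact p = 0.812).

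**Figure D4:**
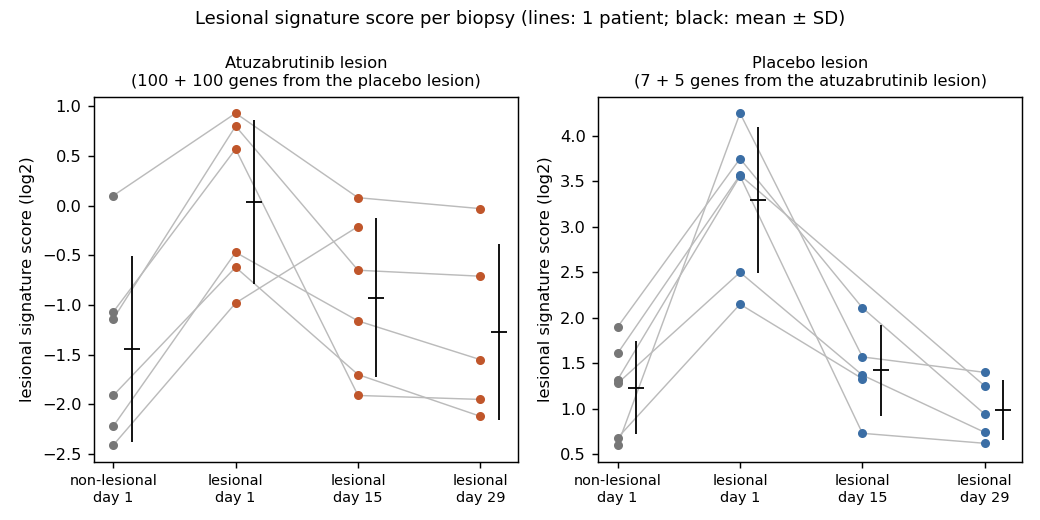
Points give the lesional score (log2, vertical axis) of each biopsy by visit in the atuzabrutinib lesion (left, 100 and 100 genes) and the placebo lesion (right, 7 and 5 genes), beside non-lesional skin scored with the same genes, with lines for patients and black marks for mean ± SD. The score was lower at day 29 than on day 1 in 5 of 5 patients in both lesions, and the panels differ in their genes and axes.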

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

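The tests chosen after the result was seen were those of handling on the day 1 visit, of the starting difference in T cell transcripts (as a part and as the whole), of exchanged lesions and of the splits for the 5 comparisons without calls, and the 3 patterns weighed here were picked after the results.

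A sample lay far from the others of its group in 12 of 252 groups tested, and chance gives about 1 in 20 (12.6 expected). These are log2 values, with the nearest other sample in brackets. In the placebo lesion of day 29, replicate 3 was highest for BTK at 7.79 (6.61), for the mast cell list at 8.15 (5.92) and for the fibroblast list at 13.44 (10.60). Replicate 4 of that group was highest for proliferation at 7.59 (6.97) and lowest for itch at 5.25 (6.42), and on day 15 lowest for the BTK list at 5.57 (6.45). Replicate 1 of the placebo lesion on day 1 was highest for dendritic cells at 8.77 (6.69). In the atuzabrutinib lesion of day 29, replicate 2 was highest for MMP12 at 9.22 (2.24), replicate 6 lowest for melanocytes at 8.25 (8.91) and replicate 4 lowest for sweat glands at 7.03 (8.81). Replicate 6 of its day 1 was highest for muscle at 7.95 (6.56), and replicate 3 of its day 15 lowest for stress at 8.31 (8.83).

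Between the lesions, camera with the preset correlation called a difference of changes for 14 lists at day 15 and 8 at day 29, none of which held with an estimated correlation. Median log2 differences at day 15 were 1.40 for T cells, 1.39 for monocytes and macrophages, 1.35 for type 2 genes, 1.16 for the sebaceous gland, 0.89 for dendritic cells, 0.87 for interferon, 0.74 for fibroblasts, 0.61 for the BTK list and 0.49 for mast cells. On the negative side they were −0.29 for melanocytes, −0.85 for muscle, −1.15 for sweat glands, −1.21 for erythrocytes and −1.98 for the hair follicle. At day 29 they were 0.85 for monocytes and macrophages, 0.65 for fibroblasts, 0.61 for type 2 genes, 0.55 for interferon, 0.21 for the BTK list, −0.37 for barrier genes, −0.62 for muscle and −1.12 for the hair follicle.

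The 1st pattern is that named genes such as FOSL1, MMP1 and SOCS3 were higher in lesional skin on day 1 and lower at day 29 in both lesions. Handling that affected every biopsy of day 1 alike was argued against as the whole of the pattern. The stress list was 0.63 higher in lesional than in non-lesional biopsies of the same visit (SD 0.49, n = 6). Such handling would cancel in this difference. Without later non-lesional libraries, a part of it in the drop by day 29 could not be told apart. For the stress list in lesional skin on day 1, depth was argued against as well. With estimated reads as a covariate that list stood at 0.70 against 0.61 without. This value covers neither the named genes of the pattern nor the drop by day 29. A stress response in the biopsy as the whole of the change could not be told apart from disease. With the stress list as a covariate the placebo hyperplasia median at day 29 was −0.91 against −1.91, and the list itself holds AP-1 genes that inflamed skin also expresses. Handling of lesional biopsies alone stays open, as does lesional inflammation that went down with time.

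The 2nd pattern is that more genes were called in the placebo lesion than in the atuzabrutinib lesion at day 29. Dependence on 1 patient fitted: without replicate 2 the ratio of the counts was 1.24, while without replicate 5 it was 1180. A starting difference could not be told apart. On day 1 the placebo lesion had 964 calls against non-lesional skin and the atuzabrutinib lesion 12, but the direct comparison of the lesions had 0. By the score with genes picked from both lesions, the day 1 difference in the 5 patients with biopsies of day 29 was −0.28 (SD 0.68). It carried a share of 0.54 of the difference of changes of 0.51. That share met the limit set beforehand for a starting difference, but the spread of the day 1 difference was wider than the difference itself. The assigned gels stay open as the biological explanation, as the labels do not state which visits were blinded or open-label, and the tested difference called no gene.

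The 3rd pattern is that the T cell list stood higher in the atuzabrutinib lesion in the difference of changes at day 15. On day 15 itself the list was 1.06 higher in the atuzabrutinib lesion (SD 0.45, higher in 5 of 5 patients, exact sign-flip p = 0.0625). A starting difference as the whole would not give this. But the value is a term of the difference for which the list was picked, so it cannot exclude that explanation. As a part, a starting difference could not be told apart, with a share of 0.28 of a mean of 1.48 (SD 1.63, n = 5). An exchange of lesions in replicate 1, whose lesions differed the most on day 1, could not be told apart: without that patient the mean was 0.79. Nor could the share of dermis, since with the fibroblast list as a covariate the median was 0.89 against 1.40. An effect of the drug stays open as a hypothesis that is not particular to T cells, since the type 2, dendritic cell and interferon lists were also higher on day 15 in 5 of 5 patients, and no gene of the list was called.

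Group labels were redrawn at random to ask whether chance gives as many calls, with the real split counted in each number of 100. As many calls as the real 1221 came in 3 splits for lesional skin (highest other 1994), as many as 175 in 1 for atuzabrutinib at day 15 (131), as many as 18 in 2 for placebo at day 15 (629), as many as 658 in 1 for atuzabrutinib at day 29 (163) and as many as 2661 in 1 for placebo at day 29 (2512). These shares are below 0.05, but the splits ignore the pairing by patient, and a split with 629 calls against 18 points to structure of the samples beyond the groups. With labels exchanged only within patients, as many calls came in 3 of 100 splits for lesional skin (highest other 1714). For atuzabrutinib at day 15 they came in 1 of 32 (131), the smallest possible share. Both shares are below 0.05, but this does not exclude chance. An exchanged split of lesional skin called more genes than the real one, and both counts were 0 without replicate 3. For placebo at day 15 and for atuzabrutinib and placebo at day 29 the 16 splits within patients are too few for a share under 0.05 (real counts 18, 658 and 2661, highest others 0, 57 and 802). For the differences of changes and the lesions on days 15 and 29 and on day 1, the real count is 0, so that all 100 splits give as many by construction and decide nothing. Their highest other counts were 1, 0, 0, 0 and 713, and the last again points to structure.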

How the results depend on the processing

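Tests chosen after seeing the data were the other pseudocounts, quantile and total scaling, the filter at 50 and the 4 covariates. Counts are of called genes in the order lesional skin (1221 in the model reported), atuzabrutinib day 15 (175), placebo day 15 (18), atuzabrutinib day 29 (658) and placebo day 29 (2661), and the cause of a change was not tested unless named. Without the replicate block, which pairs the samples of a patient, they were 11, 6, 0, 20 and 234. With only the groups compared, which leaves fewer libraries to estimate the spread, they were 490, 0, 0, 0 and 678. With the lesion as block they were 7, 0, 106 and 2269 for the changes over time. With the values of both lesions of a patient combined into their mean, which also leaves fewer libraries, the lesional count was 0. The stress covariate left 1, 0, 0, 0 and 25. Atuzabrutinib at day 15 had 84 with no filter, 116 with total scaling, 85 with the reads covariate and 60 with the olfactory covariate, which left 294 at day 29. Placebo at day 15 had 0 with no filter, 434 with voom, 254 with quantile scaling, 115 with total scaling, 104 with the filter at 50, 11 with the reads covariate and 162 with the fibroblast covariate. Leaving out each patient gave 0 to 1365, 0 to 588, 0 to 301, 1 to 893 and 744 to 2971 calls, with fewer samples in each. The block changed the call of no other comparison, and the 5 comparisons of the lesions had 0 calls in every setting. The list tests called 110 of 250 by camera, 99 without the block, 10 by fry and 0 with an estimated correlation.

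Scaling moved the direction of calls. The share of higher calls was 52% for lesional skin but 35.8% with voom, 37.3% with total and 39.4% with quantile scaling. It was 21.7% for atuzabrutinib at day 15 (48.4% with voom, 47.4% with total scaling), 61.1% for placebo at day 15 (78.3% with total scaling), 31.8% for atuzabrutinib at day 29 (63.5%, 61%) and 46.5% for placebo at day 29 (63.5%, 62.2%). Voom and total scaling put the median of all genes at 0.13 and 0.11 in the atuzabrutinib lesion at day 15 and at 0.13 and 0.12 at day 29, against 0.01, so changes there are relative to that shift. The sign of a list median differed under some scaling for 20 of 250 medians, none above 0.38 in size. The score differences had values only without replicate 1 (−0.09 at day 15 and −0.34 at day 29, both reversed) and without replicate 2 (1.61 and 1.22). In the reversed values 3 genes were left to score the placebo lesion and replicate 1 has no biopsies of day 29, so the choice of genes alone moved the value of day 29. The changes of the score, where they had a value, ran from −1.61 to −0.67 and −2.05 to −1.2 at day 15 and from −1.78 to −1.25 and −2.71 to −1.44 at day 29 for atuzabrutinib and placebo. Too few genes passed to score the atuzabrutinib lesion without replicates 3 or 6 and the placebo lesion without replicates 3, 4 or 5. Of the 261 results for named genes, 4487 values under other settings stayed called in the same direction or stayed uncalled, 1202 lost the call, 4 gained one and 1 reversed, HBEGF in the atuzabrutinib lesion at day 29 with the stress covariate (0.04). The planned DESeq2 test and its edgeR counterpart with TMM scaling were not run because the values are not whole reads. IL13 and CCL26 stayed below the filter, and whether depth or low expression kept them there was not tested.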

Other observations

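All tests of lesional skin of days 15 and 29 against non-lesional skin were chosen after seeing the data. Averaged over both lesions, no gene was called between lesional skin of day 29 and non-lesional skin of day 1 (0 calls by limma, 705 with an unadjusted p < 0.05 against 766 by chance, and 0 without any patient), nor at day 15 (0 calls, 797). Recovery of known differences was not simulated for these comparisons, so the lack of calls does not show that the skin was alike. The hyperplasia list, at 1.49 on day 1, had a median of −0.32 at day 29 and 0.29 at day 15. The T cell list stood at 0.46 at day 29 and 0.86 at day 15, the interferon list at 0.25 and 0.66, and the type 2 list at 0.22 and 0.45. None of these lists moved by fry (adjusted p = 0.96 for all 4 at day 29, and 0.91, 0.29, 0.28 and 0.29 at day 15). Camera with the preset correlation gave adjusted p = 0.009, 0.00022, 0.012 and 0.33 at day 29, and 0.3, 5.7e-13, 7.3e-17 and 2.4e-05 at day 15. With an estimated correlation none of them was called (0.94 for all 4 at day 29, lowest 0.36 at day 15). By the score, with 200 genes for the atuzabrutinib and 12 for the placebo lesion, the mean difference from non-lesional skin was −0.02 in the atuzabrutinib lesion (SD 0.61, n = 5) and −0.36 in the placebo lesion (SD 0.68, n = 5) at day 29, after 1.48 and 2.06 on day 1. The genes were picked against the same non-lesional libraries, which favours a positive difference, so these are values without a test.

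In the lesional comparison of day 1, markers of skin appendages varied more between patients than those of immune cells, which did not hold for sweat glands in the change of the atuzabrutinib lesion at day 15 (SD 0.94, against 1.76 for monocytes and macrophages). The sweat gland list had the largest median at day 29, 1.59 above non-lesional skin (camera adjusted p = 3.6e-09, but 0.68 with an estimated correlation and 0.64 by fry), and 1.44 at day 15 (0.36 and 0.29). No gene of that list was called in either. The sebaceous gland list had medians of 2.15 and 1.63 in the atuzabrutinib lesion and 0.97 and 1.52 in the placebo lesion at days 15 and 29, with no call. Its difference between the lesions on day 1 was −1.31, lower in the atuzabrutinib lesion in 6 of 6 patients (exact p = 0.0312, adjusted p = 0.6 with an estimated correlation), and the per-patient SD of its lesional difference was 3.84. The hair follicle list had a per-patient SD of 4.28 and the sweat gland list of 2.44 in that lesional comparison, against 1.28 for T cells and 1.69 for monocytes and macrophages. The largest component of the data, with 27% of the variance, had 72.6% of its own variance between patients and 3.3% between groups. It also correlated with log2 of the olfactory receptor total (r = 0.55) and of estimated reads (r = 0.37).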
